A study of Mus musculus with 5 samples.

How the data were processed

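The series holds single-cell 3′ RNA sequencing (10x Genomics) of mouse telencephalon at E16.5, dissociated with papain and sorted for red fluorescence, from Gad2-Cre/Ai14 mice: 2 control libraries labelled wild type and 3 libraries labelled Arx cKO. The labels call the animals age- and gender-matched. The protocol text writes cDKO in place of Arx cKO, so differences between the groups are read as differences between the labels, and a further deleted gene is not excluded. Nothing in the labels says whether the libraries come from separate animals or litters, so the p-values measure the spread between these libraries. Per the labels, the authors made the counts with Cell Ranger 5.0.1 against mm10, and the file headers carry the same version; the annotation release and counting options are not given in the sources used here. The deposited matrices hold UMI counts of 32285 genes for barcodes already called as cells, 6665 and 6888 in the controls and 6575, 6910 and 6785 in the libraries labelled Arx cKO. Gene positions came from GENCODE M21, which held 32158 of the 32285 gene IDs.

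Cells with fewer than 500 genes (40 and 122 in the controls; 72, 99 and 104) or with 10% or more mitochondrial UMIs (142 and 360; 354, 218 and 397) were removed. Scrublet, with an expected rate of 6%, called 210 and 169 control doublets and 187, 149 and 160 in the libraries labelled Arx cKO at a score of 0.25. Its automatic threshold failed in 3 libraries, so the fixed score was set after the data were seen. The kept cells carried 61204499 and 54009047 UMIs in the controls and 57650304, 62161258 and 61199208 in the libraries labelled Arx cKO, with median genes per cell of 3218 and 2991.5 against 3215, 3254 and 3251. The 10 most abundant genes took 10.7% and 11.3% of control UMIs and 10.8%, 10.6% and 10.5% of the others. Between libraries of a group, log2 CPM values correlated at 0.9975 to 0.9983. In the sums over all cells the chi-square per gene was 19.1 for controls and 9.52 to 12.1 for pairs labelled Arx cKO. Averaged over genes, spread between libraries thus exceeded counting error in these sums. The average does not show this for low counts or for the smaller class sums, where counting error can set the precision. Counting intervals (95%) of low counts cover counting error alone.

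Cells were clustered in scanpy 1.11.5 (Python 3.11.15, leidenalg 0.10.2, igraph 0.11.9) on 2000 highly variable genes with 30 principal components, 20 nearest neighbours and a Leiden resolution of 1. The 2316 genes that differed between genotypes in sums over all cells, Arx and sex-linked genes were left out first, to lessen the pull of genotype on the clusters. This gave 20 clusters, of which clusters 10, 11, 13 and 18 still held cells mostly of a single group. A cluster was named for 1 of 18 marker sets when at least 3 markers were detected in 10% of its cells at a log2 fold of 0.5 over the other clusters, its best score led by 0.3, its cells had a median of at least 33.3% of the median UMIs of their library, and no other class held more of its leading genes. Markers were scored from 20 CPM upwards, folds used a pseudocount of 5 CPM, and the 10 leading genes needed 50 CPM. The marker sets were fixed before the data were examined, whereas these margins were set after seeing the clusters. MGE-like neurons were clusters 0, 11 and 13, CGE-like neurons cluster 2, LGE-like striatal neurons clusters 1, 3, 5, 6 and 7, olfactory bulb-like neurons cluster 4, cortical glutamatergic-like neurons cluster 12 and cycling cells cluster 17. Unnamed clusters kept 5.51% of control and 5.78% of Arx cKO cells in cluster 8, 5.05% and 5.52% in cluster 9, 1.15% and 6.65% in cluster 10, 2.26% and 2.39% in cluster 14, 1.10% and 1.48% in cluster 15, 1.20% and 0.949% in cluster 16, 0.0080% and 0.962% in cluster 18, and 0.575% and 0.502% in cluster 19.

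UMI counts were summed per library over all kept cells and over each named class with at least 50 cells in every library. Sums over all cells mix changes within cells with changes in cell makeup, and stand beside the class sums for that reason. Genotypes were compared with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM, quasi-likelihood F test, and Benjamini-Hochberg adjustment over tested genes at 0.05. UMIs per library ranged from 10817284 to 14367162 in MGE-like, 4480191 to 6298980 in CGE-like, 23177434 to 29036548 in LGE-like striatal, 2508021 to 4025080 in olfactory bulb-like and 1620465 to 3854335 in glutamatergic-like neurons. Thinned to 1620465 UMIs per library, the tests called 1276, 643, 113, 588 and 4 genes in these classes. The difference of the genotype effect between MGE-like neurons and CGE-like or LGE-like striatal neurons was tested as the class by genotype term with library as a block. Gene lists (29, of which those with at least 5 tested members were used) were tested with camera in limma 3.58.1 on voom values at a preset correlation of 0.01, Benjamini-Hochberg adjusted over lists, and again with a correlation estimated from the data. Members of several lists also served as class markers. Class shares were compared by an exact permutation of the libraries over 10 splits, with the smaller tail doubled, and by edgeR on cell numbers. Where a control group had 0 UMIs, a fold was given as a lower bound with a floor of 3 UMIs.

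The comparisons, gene lists and named genes followed rules fixed before the data were examined. Named genes were Arx and its reported targets Ebf3, Lmo1 and Shox2 in every comparison; in all cells and each main class the 10 higher and 10 lower genes with the largest log2 fold changes among those called, with every Arx cKO library on one side of both controls and at least 20 CPM in a group, leaving out sex-linked genes and unnamed gene models; and up to 4 members of each list with the smallest p. The same rule was applied to the olfactory bulb-like and glutamatergic-like classes after their values were seen. Further genes of the lists, of the interaction tests and beside Arx were chosen after their values were seen.

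The test was tested on simulated data built from these libraries. A log2 change of 1 was recovered for 78% of changed genes in all cells and for 84%, 78%, 77% and 70% in MGE-like, CGE-like, LGE-like striatal and olfactory bulb-like neurons, a log2 change of 2 for 93%, 94%, 100%, 98% and 98%, and 0.0803% to 0.111% of unchanged genes were called. The interaction test recovered 76% and called 0.225% of unchanged genes. Each simulation changed 100 genes by each amount, and 200 for the interaction test, fewer than were called in the real data. The shares of unchanged genes called therefore do not carry over to the real comparisons.

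Alternatives tried were DESeq2 1.42.0 (its size factors in edgeR, and its Wald test), no low-count filter, a mean of at least 20 CPM in a group, the replicate number as a block, each library left out, stricter cells (1000 genes, 5% mitochondrial UMIs), doublets kept, sums thinned to the smallest total, a Leiden resolution of 0.5, clustering on all highly variable genes (675 of the 2000 differing between genotypes), and for lists fry. Class shares were also taken over the named ventral neuron and progenitor classes alone. Leaving out a control leaves 1 control library, assumed to vary like the others. Added after the data were seen were sums with equal cells per cluster, single clusters of the MGE-like and LGE-like classes, list tests in olfactory bulb-like neurons, and stricter cells and kept doublets for the interaction tests. Numerical work used numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and figures matplotlib 3.10.9.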

Results

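Single-cell RNA sequencing measured 3′ transcript ends in red-fluorescent cells sorted from the E16.5 mouse telencephalon, cortex and ganglionic eminence included, on a Gad2-Cre/Ai14 background. The groups were 2 control libraries labelled wild type and 3 libraries labelled Arx cKO. The protocol text writes cDKO where the labels write Arx cKO, so deletion of a further gene is not excluded. The deposited counts held 65398622 and 57333213 UMIs in the controls, and 61691260, 65231288 and 64795958 UMIs in the libraries labelled Arx cKO. After filtering and doublet removal, 6281 and 6252 control cells and 5978, 6452 and 6137 cells of the libraries labelled Arx cKO remained. Median UMIs per kept cell were 9426 and 8553.5 against 9590, 9445 and 9624. Levels below are counts per 1000000 UMIs (CPM) of summed cells, given as mean ± SD over 2 control and 3 Arx cKO libraries.

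Arx UMIs were present, and higher, in every library labelled Arx cKO. Across all sorted cells Arx stood at 309 and 325 CPM in the controls and at 793, 740 and 751 CPM in the libraries labelled Arx cKO. The log2 fold change was 1.25 (SE 0.06, adjusted p = 3.7e-06, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). In MGE-like neurons Arx rose from 769 ± 40.7 to 1390 ± 21.7 CPM (log2 fold change 0.83). In CGE-like neurons it rose from 554 ± 19.8 to 1314 ± 47.7 CPM (1.21), and in LGE-like striatal neurons from 110 ± 10.3 to 415 ± 32.2 CPM (1.92). The files count 3′ tags, and Arx (ENSMUSG00000035277) ends in exon 5 at X:93297163-93298357, with its 3′ UTR from 93297401, in GENCODE M21 on mm10. Which part of Arx was deleted is not given, so a tag outside that part checks nothing about the deletion. Reported targets that Arx holds down gave a separate reading of the group labels. Lmo1, a LIM-only transcriptional regulator, rose from 18.2 ± 2.48 to 499 ± 15 CPM in all sorted cells (log2 fold change 4.76). Ebf3, a helix-loop-helix factor, rose from 0.151 ± 0.109 to 11.7 ± 1.24 CPM (6.20), and the homeobox gene Shox2 from 0.0545 ± 0.0539 to 3.40 ± 0.436 CPM (5.96, on 6 control UMIs). In MGE-like neurons Ebf3 had 0 control UMIs and was at least 265-fold higher, reaching 36.1 ± 4.35 CPM (6.97 ± 1.88 CPM in cluster 0 of that class).

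**Figure D1:**
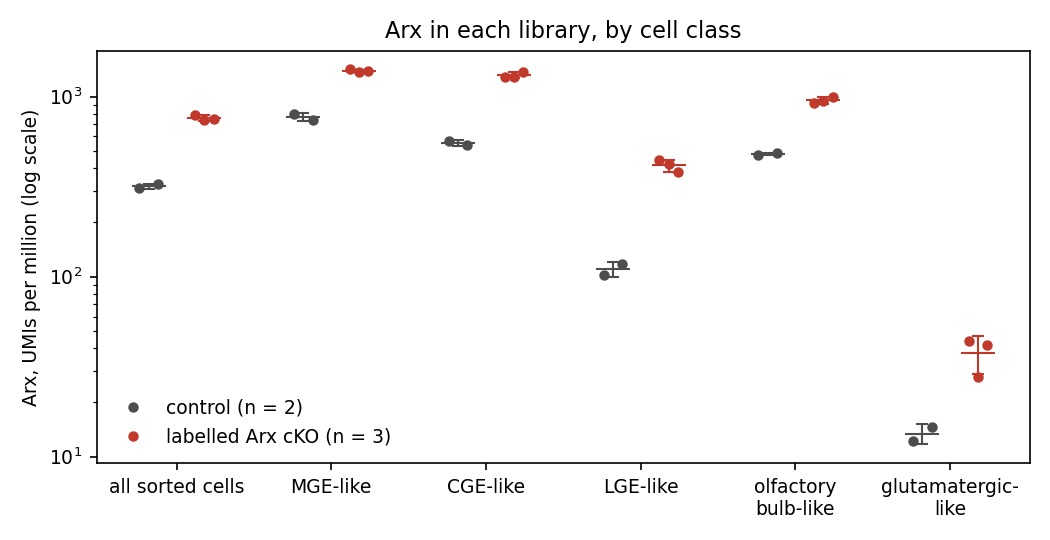
Arx level (CPM) in each library for all sorted cells and each named cell class, controls against libraries labelled Arx cKO. In MGE-like neurons the mean goes from 769 to 1390 CPM and in LGE-like striatal neurons from 110 to 415 CPM.

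In all sorted cells, Maf, Mef2c and Cxcr4 were lower and Nkx2-1, Nts and Zic1 were higher in the libraries labelled Arx cKO (n = 2 control and 3 Arx cKO libraries). Maf, a transcription factor of MGE-derived interneurons, fell from 247 ± 25.2 to 54.6 ± 1.11 CPM (log2 fold change -2.19). Mef2c, needed for interneuron maturation, fell from 438 ± 74.1 to 141 ± 9.73 CPM (-1.66), and Cxcr4, the chemokine receptor that keeps interneurons in their migratory streams, from 27.9 ± 5.83 to 3.75 ± 0.422 CPM (-2.91). Nkx2-1, the MGE identity factor that cortical interneurons switch off, rose from 7.67 ± 1.5 to 71.9 ± 2.71 CPM (3.21). The neuropeptide gene Nts rose to 139 ± 12.9 CPM (2.22) and the zinc-finger gene Zic1 from 6.52 ± 0.441 to 44.3 ± 8.24 CPM (2.75). Cadps2, a vesicle-priming factor, rose from 4.29 ± 0.284 to 43.1 ± 2.73 CPM (3.31), Tmem215 by 5.53 and the Kit ligand gene Kitl by 2.27. Among the lower genes were the scavenging chemokine receptor Ackr3 (-1.79), Id3 (-2.13), Sox8 (-1.73) and Neb (-1.61). Of 15926 genes tested, 1310 were higher and 1006 lower, and 639 of these 2316 differed at least 2-fold. Without control 1 the number was 1449. Every Arx cKO library lay on one side of both controls for 43.2% of tested genes, against 20% by chance.

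Among the gene lists in all sorted cells, most mitotic genes were lower, and the GABA list had more members called higher than lower. Of 26 cell division genes tested, 22 were lower and 0 higher (24 lower when adjusted over the list alone), with camera, Benjamini-Hochberg adjusted, at p = 5.36e-24 and adjusted p = 0.143 with an estimated correlation. Ube2c, a mitotic ubiquitin enzyme, fell from 50.2 ± 4.35 to 13.7 ± 2.25 CPM (-1.89), Top2a from 28.3 ± 6.6 to 5.41 ± 1.09 CPM (-2.40), and Cenpf and Birc5 by 1.52 and 1.77; the cluster of cycling cells held 1.07% of control and 0.340% of Arx cKO cells. GABA synthesis, transport and receptor genes were 10 higher and 1 lower of 18 (13 and 1 over the list alone, camera BH-adjusted p = 9e-07, adjusted p = 0.629 with an estimated correlation), led by Gabra3 (0.94), Abat (0.59), Slc12a5 (1.25) and Gabrb1 (1.59). Synapse and channel genes were 11 higher and 3 lower of 29 (15 and 4, camera 0.000779, adjusted p = 0.629 with an estimated correlation), with Kcnd2 up by 1.38 and the AMPA receptor subunit Gria1 down by 1.02. The pallidal or cholinergic list had 5 higher and 0 lower of 10 (5 and 0, camera 0.00177, adjusted p = 0.567 with an estimated correlation), including Zic4 (3.82) and Zic2 (3.01), and an unnamed Zic-rich cluster made up 1.15% of control and 6.65% of Arx cKO cells. Cortical glutamatergic genes were 2 higher and 9 lower of 15 (2 and 11, camera 0.00177, adjusted p = 0.629 with an estimated correlation): Tbr1 fell by 0.94, Bhlhe22 rose by 1.10 and Neurod1 by 1.17, and the glutamatergic-like class itself held 5.07% and 2.83% of cells. Olfactory bulb genes were 3 higher and 1 lower of 13 (5 and 1, camera 0.0272, adjusted p = 0.629 with an estimated correlation), with Etv1 up by 1.45 and Pbx3 by 1.06. The diencephalic list had 4 higher and 1 lower of 7 (4 and 1, camera 0.046, adjusted p = 0.629 with an estimated correlation); Hmx2 had 0 control UMIs and was at least 110-fold higher, and Otx2, also a choroid plexus gene, rose by 4.29. Oligodendrocyte lineage genes were 0 higher and 1 lower of 10 (0 and 4, camera 0.00156, adjusted p = 0.629 with an estimated correlation), the lower gene Bcas1 (-2.09) no longer passing without control 1 (-1.75). The CGE list had 0 higher and 4 lower of 14, Cnr1 (-1.13) and Adarb2 (-0.78) among them, and its camera adjusted p was 0.0606 (2 and 5 over the list alone).

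In MGE-like neurons (clusters 0, 11 and 13), Mef2c, Maf and Cxcr4 were lower and Nkx2-1, Lmo1, Lmo3 and Lmo4 were higher (n = 2 control and 3 Arx cKO libraries). Mef2c fell from 1210 ± 62.4 to 104 ± 4.13 CPM (log2 fold change -3.57, adjusted p = 1.9e-13, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Maf fell from 1039 ± 46.8 to 192 ± 1.99 CPM (-2.46), Cxcr4 from 97.6 ± 3.94 to 7.20 ± 1.32 CPM (-3.78) and Ackr3 from 282 to 61.9 CPM (-2.21). The LIM-homeobox gene Lhx6, which specifies MGE-derived interneurons, fell by less, from 400 to 260 CPM (-0.64). Nkx2-1 rose from 13.7 ± 1.35 to 228 ± 10.8 CPM (4.04), Lmo1 from 0.629 ± 0.628 to 979 ± 20.1 CPM (10.54, on 14 control UMIs), Lmo3 from 137 to 1430 CPM (3.37) and Lmo4 from 128 to 3333 CPM (4.68). The class sums mix clusters of unequal genotype makeup, cluster 13 holding 334 and 382 control cells against 15, 6 and 4 Arx cKO cells. In cluster 0 alone, chosen after the data were seen, the log2 fold changes were -2.86 for Mef2c, -2.42 for Maf, -4.18 for Cxcr4, 3.59 for Nkx2-1 and 4.51 for Lmo4.

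Further lower genes in MGE-like neurons were the phosphodiesterase Pde2a (-4.08), Efcab6 (-3.28), the AMPA receptor auxiliary subunit Cacng3 (-2.89), Id3 (-2.85), the soluble guanylate cyclase subunit Gucy1a1 (281 to 47.0 CPM, -2.60), the carbonic anhydrase Car2 (-2.57) and Edaradd (-2.54). Among the higher genes, Crym rose from 0.313 to 41.7 CPM (6.97), the cadherin Cdh6 by 6.72, Nts from 0.678 to 47.9 CPM (6.09), Lrp1b from 3.42 to 198 CPM (5.83), Magel2 by 5.72, March1 by 5.44 and the neuregulin gene Nrg1 by 5.42. Tmem215 had 1 control UMI, a ratio of 1866 (counting interval 335 to 73715). Nts reached 119 CPM in cluster 11 and 9.72 CPM in cluster 0, the latter a level that free RNA in the droplets can give. In cluster 0 alone Crym went from 0.336 to 9.17 CPM (4.68) and Lrp1b from 1.68 to 135 CPM (6.29). The somatostatin gene Sst rose from 338 to 611 CPM (0.83) and the serotonin receptor gene Htr3a, a CGE marker, from 10.1 to 75.5 CPM (2.88). Sst and Htr3a are leading genes of cluster 11, which held more Arx cKO than control cells. The class sum cannot tell their rise from a change in cluster makeup. Nor can it for the fall of Cacng3, a leading gene of cluster 13, which held mostly control cells. Of 12943 genes, 1966 were higher and 1490 lower, 1083 at least 2-fold. Libraries lay apart for 51.9% of genes (20% by chance).

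Striatal genes in MGE-like neurons were 9 higher and 1 lower of 16 (9 and 2 over the list alone, camera BH-adjusted p = 0.0012, adjusted p = 0.514 with an estimated correlation), led by the retinoic acid receptor Rarb (3.35), Rxrg (2.89), Foxp1 (0.96) and Bcl11b (0.87). Cajal-Retzius genes were 0 higher and 4 lower of 5 (0 and 5, camera 0.0012, adjusted p = 0.514 with an estimated correlation), among them Reln (-2.19), Ndnf (-2.54) and Car10 (-1.65), genes that MGE-derived interneurons also express. GABA genes split into 7 higher and 2 lower of 18 (7 and 2, camera 0.0172, adjusted p = 0.514 with an estimated correlation): Gabra2 rose by 1.06, whereas Slc6a1, the GABA transporter, fell by 0.77. Glycolysis genes were 6 higher and 1 lower of 17 (6 and 1, camera 0.0172, adjusted p = 0.56 with an estimated correlation), with Ldha up by 1.00 and Pfkp by 1.49. Synapse and channel genes were 15 higher and 6 lower of 29 (16 and 6, camera 0.0304, adjusted p = 0.56 with an estimated correlation). Kcnd2 rose by 2.88 and Kcnq3 by 2.42, and Gria1 fell by 2.45. Gria1 is a leading gene of cluster 13, which held mostly control cells, so its fall can come partly from cluster makeup. Migration and guidance genes moved both ways, 15 higher and 12 lower of 36 (15 and 13, camera 0.637), with Epha4 up by 2.29 and the netrin receptor Dcc by 3.19. LIM genes were 4 higher and 3 lower of 12 (4 and 4, camera 0.339). The MGE list itself had 5 higher and 8 lower of 15 (camera 0.126), and members of such lists also helped define the classes.

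In CGE-like neurons, Htr3a, Cnr1, Adarb2 and Cxcl14 were lower and Neurod1, Bhlhe22 and Lmo1 were higher (n = 2 control and 3 Arx cKO libraries). Htr3a fell from 229 ± 14.6 to 68.5 ± 6.31 CPM (-1.77), the cannabinoid receptor gene Cnr1 from 847 to 280 CPM (-1.63), Adarb2 from 1380 to 675 CPM (-1.07) and the chemokine gene Cxcl14 from 74.3 to 17 CPM (-2.17). Maf fell from 174 to 28.3 CPM (-2.65) and the secreted ligand gene Wnt5a from 137 to 24.4 CPM (-2.51). Neurod1, a neuronal differentiation factor, rose from 0.329 to 107 CPM (8.21), Bhlhe22 from 0.750 to 252 CPM (8.33) and Lmo1 from 33.6 ± 0.533 to 1764 ± 69.4 CPM (5.68). The integrin gene Itga4 and the homeobox gene Uncx had 0 control UMIs and were at least 328-fold and 204-fold higher, at 80.9 and 50.3 CPM.

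In CGE-like neurons the HMG-box gene Tox rose from 10.4 to 157 CPM (3.88), Cdh13 from 6.24 to 96.2 CPM (3.91), Plcxd3 by 3.80, Rasgef1b by 4.49 and Rarb by 4.19. Rgs16 (-1.98), Ntng1 (-1.95), Sdk2 (-2.22), Asic4 (-2.12), Tcerg1l (-1.93) and Cdca7 (-1.69) fell. Ntng1 stood at 24.9 and 61.4 CPM in the controls, and its log2 fold change was -1.15 without control 2. Of 11409 genes, 763 were higher and 548 lower, 476 at least 2-fold. Libraries lay apart for 38.9% of genes (20% by chance). DESeq2's Wald test called 700 genes in place of 1311.

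Striatal genes in CGE-like neurons were 7 higher and 1 lower of 14 (10 and 1 over the list alone, camera BH-adjusted p = 1.21e-06, adjusted p = 0.277 with an estimated correlation), led by Bcl11b (1.19), Foxp2 (1.18) and Six3 (2.23). LIM genes were 4 higher and 0 lower of 10 (4 and 0, camera 2.66e-05, adjusted p = 0.282 with an estimated correlation): Lmo1, Lmo3 (2.41), Lmo4 (2.36) and Lmo2 (0.91). The CGE list had 3 higher and 8 lower of 14 (5 and 8, camera 0.00106, adjusted p = 0.371 with an estimated correlation). GABA genes were 4 higher and 1 lower of 18 (9 and 1, camera 0.00502, adjusted p = 0.541 with an estimated correlation), Gabrg3 rising by 2.10 and Gabra2 falling by 1.18. Radial glia genes were 0 higher and 6 lower of 15 (0 and 6, camera 0.00804, adjusted p = 0.282 with an estimated correlation), Sox9 (-1.39) among them. Dlx and related genes were 6 higher and 3 lower of 14 (8 and 4, camera 0.0377, adjusted p = 0.42 with an estimated correlation), with Arid5b up by 1.34 and Sp9 down by 0.44. Cell division genes were 0 higher and 1 lower of 14 (0 and 1, camera 0.0474, adjusted p = 0.371 with an estimated correlation), the lower gene being the cyclin Ccnd2 (-1.07). Synapse and channel genes were 9 higher and 4 lower of 29 (10 and 5, camera 0.0474, adjusted p = 0.542 with an estimated correlation), with Gria2 up by 1.58, Syt4 by 1.93 and Nrxn1 by 1.87.

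In LGE-like striatal neurons (clusters 1, 3, 5, 6 and 7), Nts, Tac1 and Drd1 were higher and Ikzf1 was lower (n = 2 control and 3 Arx cKO libraries). Nts rose from 48.0 to 267 CPM (2.48), the tachykinin gene Tac1 from 19.8 ± 6.86 to 72.1 ± 4.58 CPM (1.87) and the D1 dopamine receptor gene Drd1 from 5.62 ± 0.831 to 26.9 ± 3.39 CPM (2.26). By cluster, mean Nts went from 0.786 to 1000 CPM in cluster 6 and from 20.8 to 199 CPM in cluster 7, against 101 to 111, 34.3 to 39.1 and 80.1 to 70.7 CPM in clusters 1, 3 and 5, where Tac1 stayed below 4 CPM. Etv1 rose from 4.51 to 27.0 CPM (2.58), the calcium-binding gene Calb1 from 82.3 to 199 CPM (1.27) and the imprinted gene Peg10 from 35.8 to 134 CPM (1.90). Ikzf1, a zinc-finger factor of striatal neurons, fell from 21.1 ± 1.87 to 3.08 ± 0.495 CPM (-2.78), Sox8 from 39.7 to 14 CPM (-1.51), and Klhl13, Gpc6, Nexn, the prohormone convertase Pcsk2 and Rph3a by 1.27, 1.26, 1.21, 1.06 and 1.00. Lmo1 rose from 9.60 to 68.9 CPM (2.84). In clusters 1 and 3 together Lmo1 went from 5.50 to 27.7 CPM, a rise that free RNA in the droplets can give. Shox2, with 0 control UMIs, was at least 86.9-fold higher. Of 13723 genes, 390 were higher and 257 lower, 187 at least 2-fold. Libraries lay apart for 31.4% of genes (20% by chance). The number of 647 dropped to 393 without control 1, 366 without Arx cKO 2 and 421 without Arx cKO 3. It was 70 in clusters 1 and 3 alone and 995 in clusters 5, 6 and 7 alone, a split chosen after the data were seen.

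GABA genes in LGE-like striatal neurons were 7 higher and 1 lower of 18 (10 and 1 over the list alone, camera BH-adjusted p = 7.9e-08, adjusted p = 0.276 with an estimated correlation), including Gabra5 (1.07), Gabrb1 (1.67) and Gabra2 (0.83). Pallidal or cholinergic genes were 3 higher and 0 lower of 5 (4 and 0, camera 9.32e-05, adjusted p = 0.276 with an estimated correlation): Zic1 rose from 0.776 to 7.51 CPM (3.29), reaching 13.5 and 19.1 CPM in clusters 6 and 7 but 3.24, 2.07 and 4.62 CPM in clusters 1, 3 and 5. In clusters 1 and 3 together Zic1 was not called (0.905 ± 0.641 to 2.66 ± 2.18 CPM). Migration and guidance genes were 10 higher and 3 lower of 38 (15 and 6, camera 9.32e-05, adjusted p = 0.44 with an estimated correlation), with the neuregulin receptor Erbb4 up by 1.43, the semaphorin receptor Nrp1 up by 0.68 and Cxcr4 down by 2.33. Olfactory bulb genes were 4 higher and 0 lower of 13 (8 and 2, camera 0.000167, adjusted p = 0.276 with an estimated correlation), with Pbx3 up by 0.96 and Tshz1 by 0.40. Synapse and channel genes were 4 higher and 1 lower of 29 (6 and 1, camera 0.0016, adjusted p = 0.44 with an estimated correlation), Kcnd2 rising by 1.10. The MGE list had 4 higher and 1 lower of 16 (5 and 2, camera 0.00794, adjusted p = 0.443 with an estimated correlation), Etv1, Calb1 and Erbb4 among the higher genes. LIM genes were 4 higher and 1 lower of 11 (5 and 2, camera 0.0272, adjusted p = 0.309 with an estimated correlation). Radial glia genes were 0 higher and 2 lower of 16 (1 and 5, camera 0.0378, adjusted p = 0.309 with an estimated correlation), Vim falling by 0.74. Striatal genes were 4 higher and 2 lower of 22 (5 and 4, camera 0.818).

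**Figure D2:**
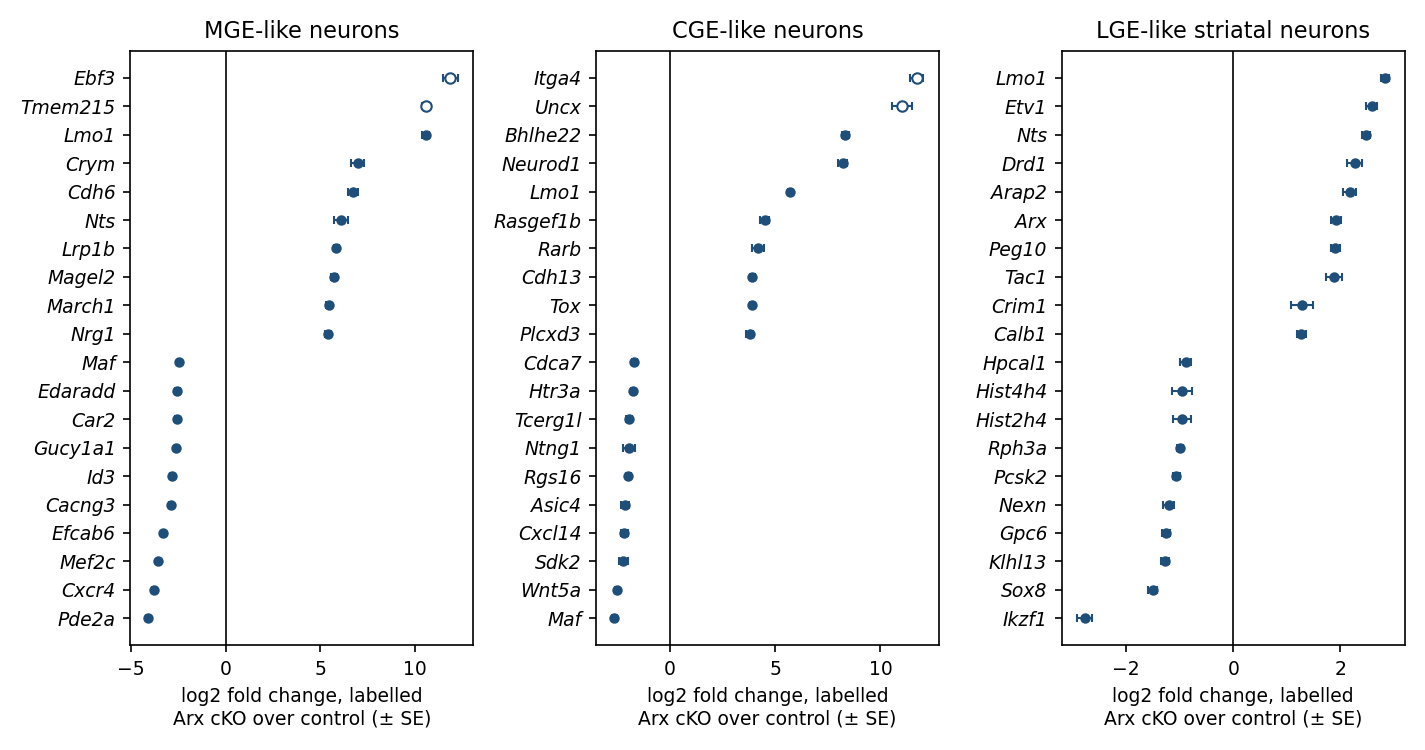
Log2 fold change (± SE) of 20 named genes in MGE-like, CGE-like and LGE-like striatal neurons, open markers standing for genes with few control UMIs. Mef2c in MGE-like neurons lies at -3.57 and Nts in LGE-like striatal neurons at 2.48.

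In olfactory bulb-like neurons, Rarb, Neurod1 and Lmo1 were higher and Fam171b and Ntm were lower (n = 2 control and 3 Arx cKO libraries). Rarb rose from 2.93 to 68.6 CPM (4.55), Neurod1 from 0.683 to 74.4 CPM (6.70), Lmo1 from 1.79 to 553 CPM (8.19), and Uncx, with 0 control UMIs, was at least 98.6-fold higher. Kctd16, which encodes an auxiliary subunit of GABA-B receptors, rose by 5.06, Igsf9b by 4.46 and the atypical cadherin Fat1 by 3.84. Fam171b fell from 161 to 36.0 CPM (-2.19), Ntm from 78.5 to 19.5 CPM (-2.02), the co-repressor Tle2 by 2.32 and Tshz2 by 1.72. Of 10493 genes, 587 were higher and 442 lower. Without control 1 the 1029 called genes became 536. Libraries lay apart for 37.8% of genes (20% by chance).

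Cell division genes in olfactory bulb-like neurons were 0 higher and 13 lower of 19 (0 and 16 over the list alone, camera BH-adjusted p = 1.63e-14, adjusted p = 0.138 with an estimated correlation), Ube2c falling by 1.49 and Cenpf from 35.9 to 11.9 CPM (-1.63). With clusters made from all highly variable genes neither gene was called (-0.54 and -0.36). The MGE list had 6 higher and 1 lower of 13 (8 and 2, camera 2.89e-06, adjusted p = 0.138 with an estimated correlation): Sox6 rose by 1.82, Cux2 by 1.46 and Calb1 by 1.57. Synapse and channel genes were 10 higher and 3 lower of 29 (11 and 3, camera 2.18e-05, adjusted p = 0.138 with an estimated correlation), with Kcnd2 up by 2.61 and Syt4 by 2.45. LIM genes were 4 higher and 0 lower of 9 (5 and 1, camera 2.18e-05, adjusted p = 0.138 with an estimated correlation), Lmo1 among them. Immediate early and stress genes were 0 higher and 6 lower of 16 (0 and 9, camera 2.57e-05, adjusted p = 0.214 with an estimated correlation), Jun falling by 0.78. Migration and guidance genes were 11 higher and 3 lower of 34 (14 and 6, camera 0.00137, adjusted p = 0.138 with an estimated correlation), with Epha5 up by 2.42 and Dcc by 2.79. The CGE list had 0 higher and 5 lower of 12 (1 and 7, camera 0.0029, adjusted p = 0.241 with an estimated correlation). Radial glia genes (1 higher and 4 lower of 16; 2 and 5 over the list alone, adjusted p = 0.138 with an estimated correlation), neurogenic genes (2 higher and 4 lower of 13; 2 and 6, adjusted p = 0.138 with an estimated correlation) and glycolysis genes (4 higher and 0 lower of 16; 7 and 0, adjusted p = 0.306 with an estimated correlation) each had a camera adjusted p of 0.00435. These lists were tested in this class after its gene counts had been seen.

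Cortical glutamatergic-like neurons, named from excitatory markers such as Tbr1 although the cells were sorted for the reporter of Gad2-Cre, held 4 changed genes of 10050 tested, with 511 before adjustment (n = 2 control and 3 Arx cKO libraries). Crym rose by 2.51, Arx from 13.4 ± 1.73 to 37.7 ± 8.83 CPM (1.51), and Cenpf and Ube2c fell by 1.81 and 1.95. Arx in this class amounted to 4.23% of its level in all sorted cells in controls and 4.95% in the libraries labelled Arx cKO, and Gad2 to 6.26% and 7.77%, ratios that free RNA in the droplets can give. Lmo1, which these neurons express, stood at 130 ± 3.53 and 186 ± 32.7 CPM (log2 fold change 0.52, adjusted p = 0.244, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The number of changed genes was 1 without control 1, 17 without control 2, 0 without Arx cKO 1, 7 without Arx cKO 2 and 2 without Arx cKO 3. Arx lost its call without control 1 (1.36), Arx cKO 1 (1.38) or Arx cKO 3 (1.42), and Cenpf (-1.54, -1.68 and -1.73) and Ube2c lost theirs without the same libraries. The class of cycling cells, at 20 to 22 cells in each library labelled Arx cKO, was too small for gene tests.

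Several genes went in opposite directions in MGE-like and CGE-like neurons, tested as a class by genotype interaction blocked on library. Htr3a rose by 2.88 in MGE-like neurons and fell by 1.77 in CGE-like neurons (difference 4.64, SE 0.12, adjusted p = 3.4e-28, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Wnt5a (1.19 and -2.51) and Sst (0.83 and -1.21) went the same way. Gucy1a1 (-2.60 and 1.69) and Cdh13 (-1.03 and 3.91) went the other way. Htr3a and Sst are leading genes of MGE-like cluster 11, which held 110 and 110 control cells against 322, 395 and 370. Their rise in the MGE-like sum can thus come partly from cluster makeup, and their changes within single clusters of that class are not given here. Mef2c fell by 3.57 and 0.84, a difference of -2.73, whereas Maf fell by 2.46 and 2.65 with no difference passing (adjusted p = 0.21, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Both are leading genes of MGE-like cluster 13, which held mostly control cells, so cluster makeup can add to their falls in the MGE-like sum. Of 11314 genes, 1500 differed between these classes, including 81 that changed in opposite directions. Of the 2145 genes called in MGE-like neurons and not in CGE-like neurons, 736 differed in the interaction.

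Between MGE-like and LGE-like striatal neurons 2960 of 12649 genes differed, 60 with opposite changes. The neurofilament genes Nefl (3.91 and -0.78) and Nefm (2.16 and -0.79), the glypican gene Gpc6 (1.94 and -1.26) and Foxp1 (0.96 and -0.38) rose in MGE-like and fell in LGE-like striatal neurons. Lmo4 rose by 4.68 and 0.50. Of the 2889 genes called in MGE-like neurons and not in LGE-like striatal neurons, 1968 differed in the interaction.

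Cell classes also made up different shares of the sorted cells. Cycling cells, marked by Top2a and Cenpf, went from 1.07 ± 0.0868% to 0.340 ± 0.0291% (ratio 0.318; 71 and 63 cells against 22, 20 and 21). Glutamatergic-like neurons went from 5.07 ± 0.739% to 2.83 ± 0.161% (0.558), CGE-like neurons from 11.2 ± 0.0086% to 8.23 ± 0.583% (0.738), LGE-like striatal neurons from 40.6 ± 2.96% to 35.2 ± 1.56% (0.867) and MGE-like neurons from 19.1 ± 1.01% to 22.5 ± 1.43% (1.18). Olfactory bulb-like neurons were at 6.24 ± 0.95% and 6.73 ± 0.717% (1.08). Shares of a library are tied together, so the rise of some clusters lowers the others. Over the named ventral neuron and progenitor classes alone, the ratios were 0.929 for LGE-like striatal, 0.790 for CGE-like and 1.26 for MGE-like neurons. They were 1.16 for olfactory bulb-like neurons and 0.341 for cycling cells. With clusters made from all highly variable genes the MGE-like ratio over all kept cells was 0.977 and the olfactory bulb-like ratio 0.709. The latter was 0.974 without control 2. That MGE-like share left out an unnamed cluster scoring best as MGE-like, with 3 and 2 control cells against 187, 178 and 232. Cluster 9, left unnamed for its low UMIs, also scored best as MGE-like. It held 2.21% and 7.89% of control cells against 5.05%, 5.24% and 6.27%. With its cells counted as MGE-like, control 2 would no longer lie below every Arx cKO library. Within the MGE-like class, cluster 13 held 334 and 382 control cells against 15, 6 and 4, while cluster 0 went from 708 and 744 to 1100, 1022 and 931 cells and cluster 11 from 110 and 110 to 322, 395 and 370 cells. An unnamed cluster led by Zic1, Zic4 and Zic2 (cluster 10) had 85 and 59 control cells and 351, 398 and 486 cells in the libraries labelled Arx cKO. Another, led by Neurod1 and Ebf2 (cluster 18), had 0 and 1 control cells and 58, 72 and 49. Cluster 18 scored best as CGE-like (1.32), too near its neurogenic progenitor-like score (1.06) to be named. The CGE-like share therefore leaves its cells out. At a Leiden resolution of 0.5 the CGE-like ratio was 0.823. With 10 possible splits of the libraries, and the smaller tail doubled for a two-sided test, the exact permutation p cannot go below 0.2, the value reached by these classes apart from olfactory bulb-like neurons (0.6). edgeR's quasi-likelihood test on cell numbers with Benjamini-Hochberg adjustment gave adjusted p = 0.000923 for cycling cells, 0.0225 for glutamatergic-like, 0.0378 for LGE-like striatal, 0.0395 for CGE-like, 0.0625 for MGE-like and 0.78 for olfactory bulb-like neurons.

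**Figure D3:**
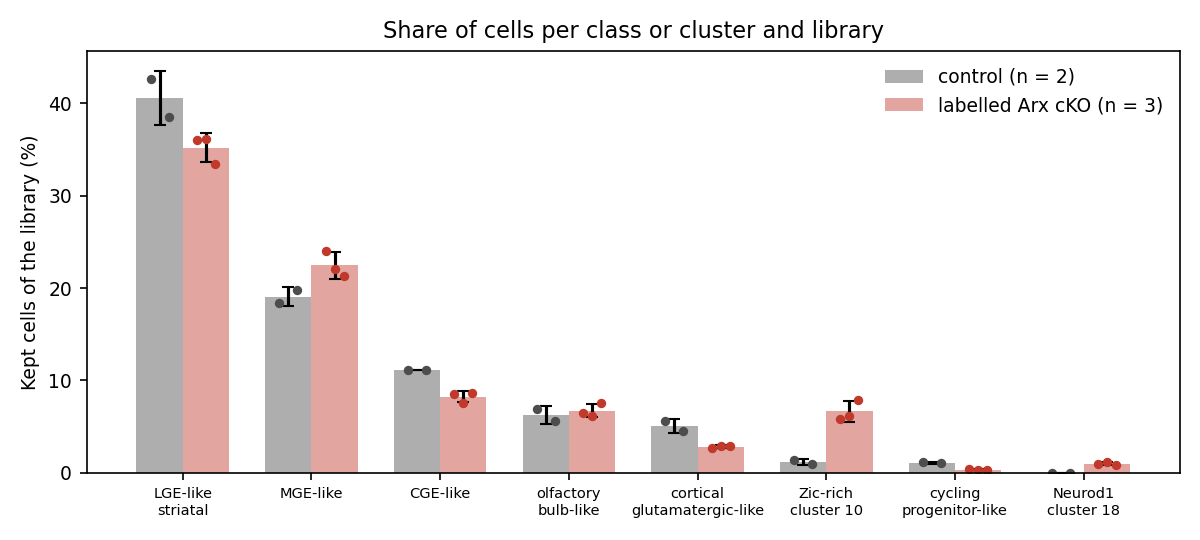
Share of kept cells (%) in each named class and in unnamed clusters 10 and 18, per library. The other unnamed clusters are not drawn. Cycling cells go from 1.07% to 0.340% and the Zic-rich cluster 10 from 1.15% to 6.65%.

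Genes beside Arx on chromosome X were higher in the libraries labelled Arx cKO. Pola1, a DNA polymerase subunit gene 6410 bp past the end of Arx on the opposite strand, rose from 38.3 to 85.8 CPM in MGE-like neurons (1.14) and by 1.82 in CGE-like neurons. The kinase gene Pdk3 rose from 21.4 to 38.4 CPM in MGE-like and from 12.8 to 36.7 CPM in CGE-like neurons, and Pcyt1b by 0.65 and 0.74. Zfx (-0.10 and 0.09), Eif2s3x (0.04 and -0.06) and Klhl15 (0.32 and -0.14) were not called. In MGE-like neurons 3 of the 6 tested genes within 1 Mb were higher.

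**Figure D4:**
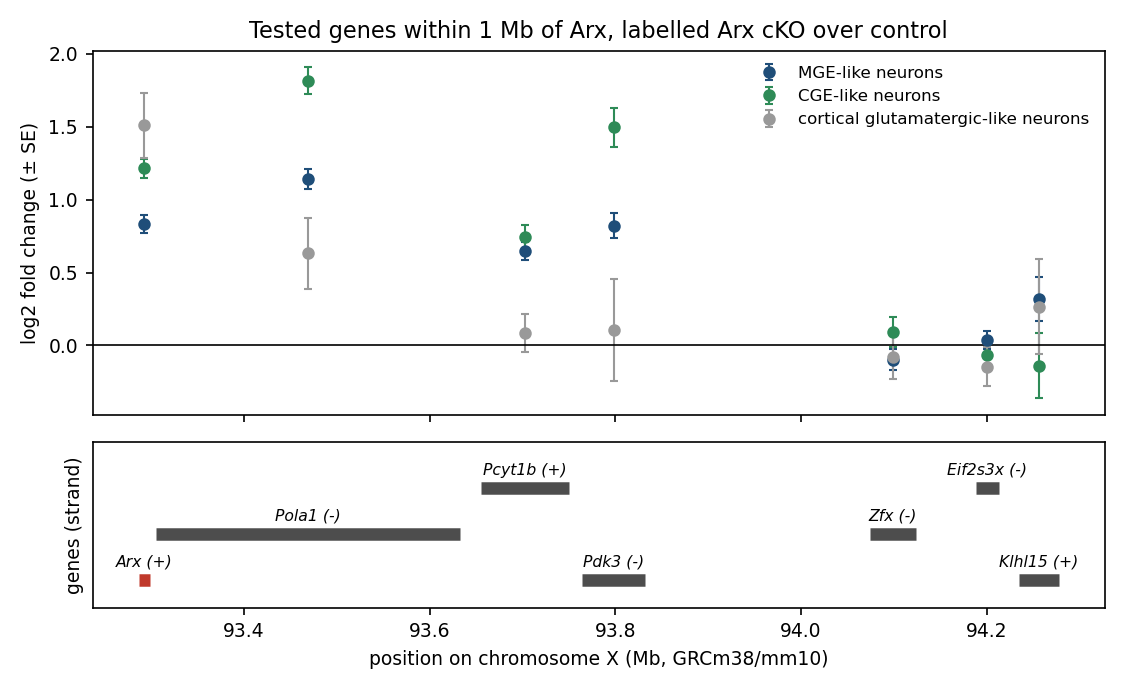
Log2 fold change of genes along chromosome X around Arx, for MGE-like, CGE-like and cortical glutamatergic-like neurons. In MGE-like neurons Pola1 lies at 1.14, Pdk3 at 0.82 and Pcyt1b at 0.65, and Zfx lies at -0.10.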

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

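The tests weighed below were all chosen after the patterns had been seen.

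The genotype effect differed between classes by the test of the difference itself, which set these results apart: 1500 genes differed between MGE-like and CGE-like neurons, 26 of them named genes, and 2960 between MGE-like and LGE-like striatal neurons, 31 of them named genes. For Arx the log2 fold change in MGE-like neurons lay at -0.38 relative to CGE-like and at -1.09 relative to LGE-like striatal neurons. For Lmo1 the differences were 4.86 and 7.71. Within the LGE-like striatal class, 778 of 12197 genes differed between clusters 1 and 3 and clusters 5, 6 and 7. Of the unnamed clusters, which the class comparisons did not use, clusters 10 and 18 stood above their level in the controls, with 6.65% and 0.962% of Arx cKO cells.

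Arx UMIs were higher in every library labelled Arx cKO. Inverted labels are argued against by the 3 reported targets, each higher in every Arx cKO library than in both controls, and a shift of cells towards Arx-rich classes by a log2 fold change of 1.24 with equal cells per cluster. A change along the chromosome around Arx remains open: the median log2 fold change of the genes within 1 Mb lay at percentile 99.83 of 10000 random lists in MGE-like (0.48), 99.93 in CGE-like and 99.97 in LGE-like striatal neurons, but at 94.46 in olfactory bulb-like neurons and at 83.71 in glutamatergic-like neurons. In olfactory bulb-like neurons Pola1 was not called, whereas Pdk3 (1.06) and Pcyt1b (0.61) were called higher. In LGE-like clusters 1 and 3, with Arx near its background, Pola1 stood at 12.6 CPM in controls and 13.3 CPM in the libraries labelled Arx cKO. An effect of the genotype on Arx transcription itself also stays open and was not tested, and the deleted part of Arx is not given.

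The Zic-rich cluster 10 held 1.15% of control and 6.65% of Arx cKO cells. Free RNA is argued against, since the rise of Zic1 in glutamatergic-like neurons was 0.9249% of its rise over all sorted cells. More tissue of a neighbouring region in the Arx cKO dissections cannot be told apart from a genotype effect: the difference of the mean shares was 2.688 times the widest range within a group, but the labels do not say how the libraries were dissected. Within the cluster Npy fell from 1292 ± 141 to 65.8 ± 14 CPM, a change that could come from either.

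Few genes changed in LGE-like clusters 1 and 3, where Arx lay near its background (13.0 ± 2.9 CPM in controls), with 70 called against 995 in clusters 5, 6 and 7 (Arx 213 CPM). Lower depth is argued against: at equal UMIs clusters 5, 6 and 7 held 19.69 times as many changed genes, 315 against 16. Changes that follow the expression of Arx would give a genotype effect differing between these sets of clusters, and the 778 genes may reflect that, although the sets also differ in much else.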

How the results depend on the processing

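In all sorted cells 2316 genes were called; a mean of 20 CPM in a group, which tests fewer genes, gave 1029, leaving out each library 1449 to 2210, and equal cells per cluster (chosen after seeing the data) 1465. MGE-like neurons (3456) moved by over 1.5 times at 20 CPM (2026) and when thinned to 1620465 UMIs per library (1276). Cluster 0 alone, also chosen later, gave 2715. CGE-like neurons (1311) gave 700 with DESeq2's Wald test and 849 at 20 CPM. LGE-like striatal neurons (647) gave 1224 without a low-count filter, 327 at 20 CPM, 366 to 620 with a library left out and, chosen later, 70 in clusters 1 and 3 and 995 in clusters 5, 6 and 7. Olfactory bulb-like neurons (1029) gave 466 with DESeq2, 677 at 20 CPM, 536 to 876 with a library left out, 1561 at resolution 0.5 and 614 with clusters from all highly variable genes, settings that also change which cells the class holds. Glutamatergic-like neurons (4) gave 1 with DESeq2, 60 without a filter, 0 to 17 with a library left out, 13 with doublets kept, 1 with clusters from all highly variable genes and 2 thinned. Apart from the filters, which change the genes tested, the cause was not tested. The interaction counts stayed at 1094 to 1562 and 2044 to 2984.

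The MGE-like share ratio reversed to 0.977, and the olfactory bulb-like ratio to 0.709, with clusters from all highly variable genes, and the latter to 0.974 without control 2 (0.974 to 1.21 over libraries left out). The MGE-like share then left out an unnamed cluster scoring best as MGE-like (0.878), with 3 and 2 control cells against 187, 178 and 232. Counting it as MGE-like would undo that reversal, though libraries of both groups would overlap. The cause of the olfactory bulb-like reversals was not tested. edgeR on cell numbers called CGE-like (0.738), LGE-like striatal (0.867), cycling (0.319) and glutamatergic-like (0.558) ratios, which 10 splits cannot. Single genes reversed for Ttr in all sorted cells without control 2 (10.78, and -1.24 without control 1), and with clusters from all highly variable genes for Prox1 in MGE-like (-0.74) and Pbx3 (-0.14) and Zic3 (-0.70) in olfactory bulb-like neurons. Lists reversed for cortical glutamatergic genes in MGE-like neurons with fry (directional, 0.000811) and stress genes in LGE-like striatal neurons with the replicate block (0.0210). Of 627 gene and class combinations followed, 406 were called; 48 of these lost their call with DESeq2, and 20 to 59 without 1 library. With a control left out, the folds of Ebf3, Shox2 and Tmem215 in all sorted cells, of Lmo1, Cdh6, Crym and Tmem215 in MGE-like and of Bhlhe22 and Rarb in CGE-like neurons, all with low control levels, moved by over 1.5 times and stayed called. All 39 lists that passed lost their call with an estimated correlation.

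With the replicate number as a block, 1593 genes were called in all sorted cells, 2784 in MGE-like, 777 in CGE-like, 511 in LGE-like striatal, 929 in olfactory bulb-like and 3 in glutamatergic-like neurons. In all sorted cells, deviations of same-numbered libraries correlated at 0.016 and 0.18 and of others at -0.18 to 0.17. In the classes same-numbered libraries correlated at -0.078 to 0.037. With 2 controls, each control's deviation mirrors the other's, so these values cannot decide whether the numbers pair the libraries. The block takes 2 of the 3 residual degrees of freedom and leaves Arx cKO 3 out of the contrast.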

Other observations

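In the Zic-rich cluster 10, which carried no class name, Npy and Tac1 were lower and Lmo1 and Zic4 were higher (n = 2 control and 3 Arx cKO libraries, 944767 to 6767195 UMIs each). The neuropeptide Y gene Npy fell from 1292 ± 141 to 65.8 ± 14 CPM (log2 fold change -4.25; adjusted p = 5.3e-10, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), Tac1 from 127 to 11.8 CPM (-3.41), and Nos1, the neuronal nitric oxide synthase gene, by 4.12. Sst fell by 1.44 and Lhx6 by 1.19. Lmo1 rose from 22.1 to 303 CPM (3.80), Zic4 from 27.5 to 178 CPM (2.77), Crym from 1.59 to 25.9 CPM (4.32), Nkx2-1 from 38.4 to 79.4 CPM (1.06) and Arx from 202 to 600 CPM (1.60). Neurod1, at 0 control UMIs, reached 82.6 ± 5.02 CPM. In all, 168 genes were higher and 221 lower. The cluster held 85 and 59 control cells against 351, 398 and 486 in the libraries labelled Arx cKO. A different mix of cells within it can also give such differences, which was not tested.

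Clusters 5, 6 and 7 of the LGE-like class, all with the striatal marker Isl1, held most of the changes of that class. In their sum Nts rose from 25.2 ± 0.341 to 442 ± 6.39 CPM (4.13), Drd1 from 11.2 to 50.1 CPM (2.17), Tac1 from 39.3 to 136 CPM (1.79), Etv1 from 6.59 to 48.2 CPM (2.87) and Calb1 from 43.1 to 224 CPM (2.38), while Ikzf1 fell from 43.1 to 5.90 CPM (-2.88), Sox8 from 69.7 to 19.9 CPM (-1.81) and Foxp1 by 0.76. In cluster 6 alone, Nts stood at 0.786 ± 0.637 CPM in controls and 1000 ± 124 CPM in the libraries labelled Arx cKO, and in cluster 5 at 80.1 ± 5.65 and 70.7 ± 39.1 CPM. In the Drd2 and Penk rich clusters 1 and 3, Penk rose from 188 to 275 CPM (0.54) and Pcp4 by 0.53, and Meis1 fell from 76.8 to 46.5 CPM (-0.73).

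The Neurod1-led cluster 18 had Lmo1 at 1059 CPM in the libraries labelled Arx cKO. At a Leiden resolution of 0.5, a cluster of 759 Zic and Lhx8 cells met the naming rule for pallidal or cholinergic-like neurons, with 0.939% and 0.672% of control and 2.86%, 3.29% and 4.48% of Arx cKO cells. With clusters from all highly variable genes, neurons split by genotype in several classes. Among MGE-like neurons 1 cluster held 2 and 2 control cells against 1187, 1173 and 1038, and another 1082 and 1151 against 11, 11 and 10. Among CGE-like neurons the numbers were 678 and 690 against 38, 27 and 28, and 2 and 12 against 467, 435 and 480, and an LGE-like striatal cluster held 438 and 433 against 3, 4 and 2. The astrocyte gene Gja1 rose by 3.89 in all sorted cells, with the astrocyte list at 2 higher and 0 lower of 8 (camera BH-adjusted p = 0.527). The median log2 fold change of genes on chromosome X exceeded the autosomal median by 0.071 in MGE-like neurons.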
